A study of Sesamum indicum with 6 samples.

How the data were processed

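Seeds of a black and a white sesame (Sesamum indicum) cultivar were compared by RNA sequencing of total RNA, with 3 libraries per cultivar that the series' design text calls biological repeats. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with NEB reagents. The labels give neither the cultivars' names nor the age of the seeds, and nothing in them says that a replicate number links a black and a white library.

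Per the file headers, the authors deposited a count and an FPKM value per gene and library in a single table of 27338 genes, together with their own log2 fold change of black over white, p-value and adjusted p-value. The submitters' processing notes list Trimmomatic, HISAT2, StringTie, featureCounts 2.0.1, RSEM 1.3.1 and DESeq2, without the role of each, and whether counting used strand is not given in the sources used here. The deposited counts are whole numbers. The deposited FPKM values equal the count per base of gene length divided by the library's DESeq2-type size factor and by the geometric mean of the library totals, to within 3.2e-15 of each library's highest value. They are thus scaled by size factors and not by each library's own total. In the authors' deposited columns, 3549 genes with a total count of 0 or 1 have no log2 fold change, and 96 genes have no p-value while their adjusted p-value is written as 1. A further deposited file that repeats the gene annotation was not used here.

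All 26665 genes with a RefSeq identifier had the start and end that the reference table gives for the assembly S_indicum_v1.0, so positions are given on that assembly, with its linkage groups. The other 673 loci were added by the authors. Gene descriptions come from the deposited table. Reads of near-identical gene copies, as in the storage protein, ribosomal protein and lipid-transfer protein families, and reads of overlapping or antisense genes may be split between genes, so values of single members of such families are uncertain.

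Differences between cultivars were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, 1 factor with white as reference), two-sided, with Benjamini-Hochberg adjustment over the 19763 genes tested. Genes were called at an adjusted p under 0.05, and the count of genes differing at least 2-fold adds an absolute log2 fold change of 1 or more after the test. Standard errors of log2 fold changes were taken as the absolute change over the square root of the quasi-likelihood F. The common biological coefficient of variation was 0.243. Means and SDs of FPKM are over the 3 libraries of a cultivar. A fold against a cultivar whose 3 libraries are all at 0 was computed against 3 counts over those libraries together and is a lower bound, and ratios with 1 to 3 counts carry an exact 95% Poisson interval. Shares of counts in single libraries carry 95% Wilson intervals. Bounds and intervals cover counting error only. Both cultivars were counted on the same gene models, so a count of 0 does not by itself show that a gene is not expressed.

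Before the data were examined, 36 gene lists were fixed as text patterns on gene descriptions, and the rule for named genes was set. It took (a) the 6 genes with the largest log2 fold change in each direction among called genes with no overlap between the cultivars' libraries, a mean FPKM of 5 or more in the higher cultivar and an informative description, (b) from each list the 2 called members with the smallest adjusted p and the member with the highest mean FPKM, and (c) every tested member of the lists for polyphenol oxidase and for sesamin synthesis P450. The rule gave 109 genes. Members under (b) of lists whose test did not pass were left out, except for the 3 flavonoid and seed pigment lists, an exception made after seeing the data. Genes outside the rule are named as chosen after their values were seen. Lists with 5 or more tested members (33 of 36) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. The pattern for sesamin synthesis P450 matched no description. Terms of GO or KEGG were not analysed here.

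The alternatives fixed in advance were DESeq2 1.42.0, other scalings (RLE, library totals), no filter and a stricter filter on low counts (a CPM of 5 or more in 3 libraries). They also held limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of 1 or more in 3 libraries, a replicate block, leaving out each library in turn, and, for lists, an estimated correlation and fry. Library totals without the 100 most abundant genes, and library totals for the gene lists, were added after seeing the data.

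The procedures were tested on simulated data drawn from the real gene means, dispersions and library sizes. For the comparison of black with white on 19480 simulated genes, edgeR recovered 39.4% of genes changed 2-fold and 81.1% of those changed 4-fold, with 9 false calls among 125. On the same simulated genes DESeq2 recovered 58.6% and 85.3%, with 40 false calls among 179. Only 99 genes were changed 2-fold and 95 were changed 4-fold there, as many up as down by design, with no shift in the storage protein share. In the data 5937 of 19763 tested genes were called. The simulated shares may therefore not hold for the data, and the scaling was not put to the test. In a separate simulation of 19469 genes, a planted list of 40 genes raised 1.5-fold was called by camera, and 0 of 20 random lists were. Genes were drawn independently there, so it does not test camera on lists whose members vary together. The cytosolic ribosomal protein list, for instance, had an estimated correlation of 0.893. Library totals ran from 18063717 to 25664204 counts, so 3 counts in a library correspond to 0.117 to 0.166 CPM. Replicates within a cultivar differed far beyond counting noise (mean chi-square per gene between 26.4 and 54.1 on 1 degree of freedom), so no library appears to have been deposited more than 1 time.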

Results

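Gene expression was measured in seeds of a black and a white sesame cultivar, with 3 libraries each. The black libraries held 25664204, 20548754 and 23142336 counts and the white libraries 18063717, 21317312 and 21485801. The comparison asks which genes differ in transcript level between seeds of the 2 cultivars. On the log2 CPM scale (CPM, counts scaled to a common library size), the first principal component held 69.6% of the variance and separated the cultivars. The second (12.04%) set black replicate 1 apart from the other libraries.

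Called genes were mostly lower in black than in white seeds in the lists for fatty acid synthesis (31 of 38 tested members), storage proteins (14 of 26), suberin, cutin and wax (57 of 137) and cell walls (68 of 190). They were mostly higher in black in the list for cytosolic ribosomal proteins (162 of 214). These 5 lists passed camera with a preset correlation, and 0 of them passed with an estimated correlation (adjusted p = 0.46 to 0.498). Of 19763 genes tested with edgeR's quasi-likelihood test, 5937 were called at an adjusted p under 0.05. Of these, 2715 were higher in black and 3222 higher in white seeds. At least 2-fold differences were found for 2621 genes, 510 higher in black and 2111 higher in white. The libraries of the cultivars did not overlap for 9482 of the tested genes (48.0%), where chance gives 10%. Scaling by library totals alone moved the median log2 fold change by 0.22 and gave 5599 genes higher in black and 2423 higher in white. The medians of the gene lists given below moved up with it, for instance from -0.26 to -0.04 for the defence list. Totals without the 100 most abundant genes, added after seeing the data, gave 1886 and 3736. Leaving out white replicate 2 left 3433 called genes (1747 at least 2-fold), and leaving out black replicate 2 left 3630. For each named gene that was called, all 3 libraries of the higher cultivar lay above the 3 of the other unless stated.

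Seed storage proteins, which supply nitrogen and sulfur to the seedling, took 5.96%, 7.22% and 3.90% of all counts in the black libraries and 23.4%, 26.6% and 19.1% in the white. The 95% Wilson intervals of these shares reach at most 0.0195 percentage points to either side. Of 26 tested storage protein genes, 14 were higher in white, 0 higher in black and 12 not called (14 and 1 when adjusted over the list alone), with a median log2 fold change of -0.70. At an unadjusted p under 0.05, 3 were higher in black, and DESeq2 called 1 higher in black. The most abundant, the 2S seed storage protein 1-like gene LOC105174860 (linkage group 12, 767834 to 768559), had 11940 ± 3449 FPKM in black and 47910 ± 8119 in white (SD, n = 3 each; log2 fold change -1.99 ± 0.31 SE, edgeR adjusted p = 0.00242). Its call was lost in both limma fits (adjusted p = 0.0614 and 0.0722, and 7.94e-19 to 0.0722 over all alternatives). The 2S albumin genes LOC105178074 and LOC105174067 had log2 fold changes of -2.49 ± 0.28 (adjusted p = 0.000527) and -2.20 ± 0.28 (adjusted p = 0.000943). A further 2S gene, LOC105174824 (linkage group 12, 585325 to 585987), was chosen after its values were seen. It had 10.3, 1.79 and 189 FPKM in the black libraries and 20800, 21320 and 9806 in the white (log2 fold change -8.00 ± 1.54, adjusted p = 0.00605), and -11.43 without black replicate 3. The list passed camera (adjusted p = 0.0125), but not with an estimated correlation (adjusted p = 0.46).

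**Figure D1:**
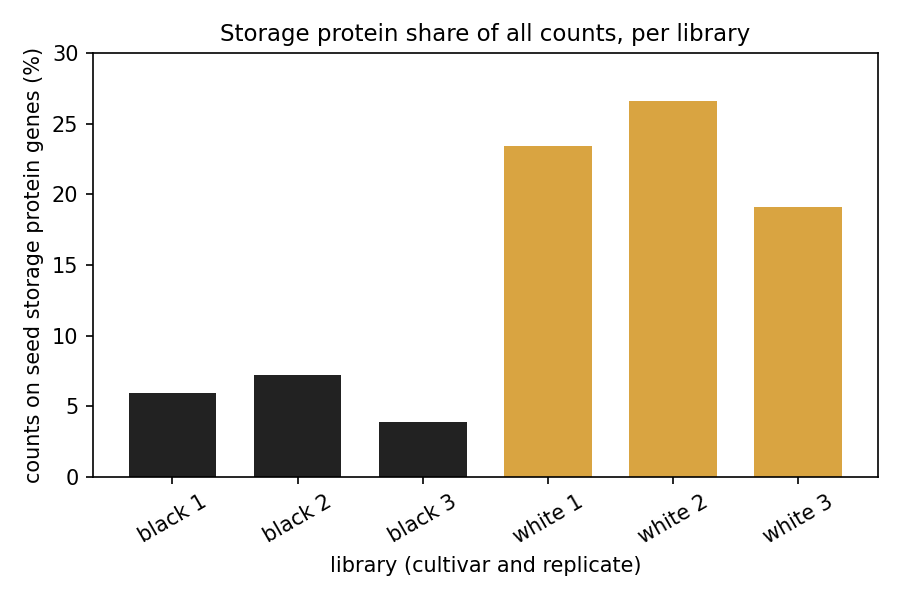
Percent of each library's counts on seed storage protein genes (y axis) for the 3 black and 3 white libraries (x axis, 1 bar per library). The black libraries lie between 3.90% and 7.22% and the white libraries between 19.1% and 26.6%.

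Fatty acid synthesis in the plastid had the lowest median among the tested lists in the fit of all libraries. Of 38 tested members, 31 were higher in white, 0 higher in black and 7 not called (33 and 0 when adjusted over the list alone), with a median log2 fold change of -1.51. None was higher in black at an unadjusted p under 0.05 or with DESeq2. The enoyl-ACP reductase genes LOC105159689 and LOC105162497, which act in the last reduction of each elongation cycle, had log2 fold changes of -3.51 ± 0.22 (adjusted p = 5.6e-05) and -4.21 ± 0.31 (adjusted p = 0.000109). The acyl carrier protein gene LOC105156924 had 31.3 ± 5.14 FPKM in black (SD, n = 3) and a log2 fold change of -2.83 ± 0.25 (adjusted p = 0.000211). The list passed camera (adjusted p = 1.01e-16), but not with an estimated correlation (adjusted p = 0.46). Without black replicate 1 its median was -1.50, above that of the general phenylpropanoid list (-1.99).

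Of 30 tested genes of fatty acid desaturation and elongation, 14 were higher in white, 0 higher in black and 16 not called (15 and 0 when adjusted over the list alone; median log2 fold change -0.64). None was higher in black at an unadjusted p under 0.05 or with DESeq2. FAD2, the omega-6 desaturase that makes linoleic from oleic acid, had 8.49 ± 3.92 FPKM in black and 168 ± 54.6 in white (SD, n = 3 each; log2 fold change -4.29 ± 0.40, adjusted p = 0.000261). The 3-ketoacyl-CoA synthase gene LOC105169646 had a log2 fold change of -4.65 ± 0.43 (adjusted p = 0.000255). For triacylglycerol assembly and oil bodies, 25 of 54 members were higher in white, 6 higher in black and 23 not called (25 and 8 when adjusted over the list alone; median -0.48, and -0.30 without black replicate 2). The oleosin gene LOC105177100, a coat protein of oil bodies, had 5033 ± 132 FPKM in black and 13980 ± 1444 in white (adjusted p = 0.00144). The cholinephosphotransferase gene LOC105158376 had a log2 fold change of -2.77 ± 0.27 (adjusted p = 0.000278). In the other direction, the cytosolic diacylglycerol acyltransferase 3 gene LOC105167876 had 70.4 ± 6.36 FPKM in black and 32.3 ± 3.27 in white (adjusted p = 0.000649). Both lists passed camera (adjusted p = 1.49e-05 and 0.00299), but not with an estimated correlation (adjusted p = 0.46 for each).

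Of 16 tested genes that matched the text pattern for regulators of the embryo and of seed filling, 7 were higher in white. Of the others, 1 was higher in black and 8 were not called (the same counts when adjusted over the list alone). Their median log2 fold change was -0.73, with -1.16 and -1.20 without black replicates 2 and 3 and -1.43 without white replicate 3. The WRI1-like gene LOC105172214 (linkage group 10, 8410169 to 8416351), whose Arabidopsis counterpart activates fatty acid synthesis genes, had 0.826 ± 0.220 FPKM in black and 43.5 ± 13.9 in white (SD, n = 3 each; log2 fold change -5.70 ± 0.31, adjusted p = 5.24e-05). The NF-YB6 gene LOC105175231, of the LEAFY COTYLEDON1 family, had a log2 fold change of -2.85 ± 0.19 (adjusted p = 6.62e-05). Another WRI1 gene, LOC105162419 (-4.35), the FUS3-like gene LOC105177478 (-3.19) and the AGL15 gene LOC105172132 (-2.56), chosen after their values were seen, were also called lower in black. The most abundant member, the LEC14B gene LOC105163208, had 39.2 ± 5.14 and 35.8 ± 1.36 FPKM (adjusted p = 0.441). It matched the pattern by the letters of its name, and its description names no role in the embryo. The list passed camera (adjusted p = 0.0241), but not with an estimated correlation (adjusted p = 0.46).

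**Figure D2:**
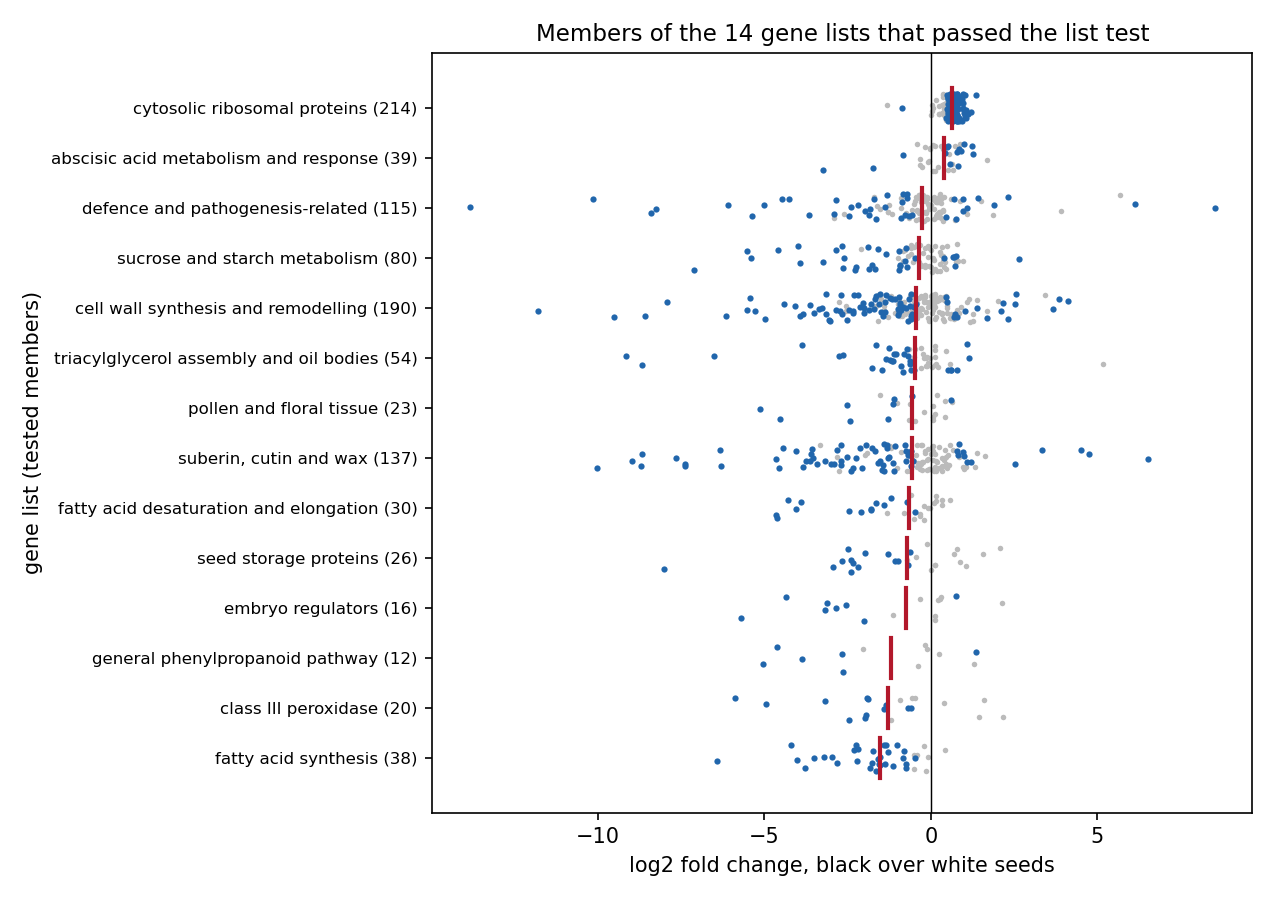
Log2 fold change of black over white seeds (x axis) for each tested member of the 14 gene lists that passed the list test (y axis, number of tested members in parentheses), with called genes in blue, genes not called in grey and list medians as red bars. The medians run from -1.51 for fatty acid synthesis to 0.64 for cytosolic ribosomal proteins, and points of genes at 0 counts in a cultivar are fitted values, not measured folds.

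The list for suberin, cutin and wax, which form lipid barriers such as those of seed coats, had 57 of 137 members higher in white. Of the others, 12 were higher in black and 68 not called (63 and 14 when adjusted over the list alone; median -0.56). Its text pattern also took all GDSL esterase and non-specific lipid-transfer descriptions, which name no role in these barriers. The CYP86B1-like gene LOC105156099, of a P450 family that hydroxylates very-long-chain fatty acids, had 0.318 ± 0.151 FPKM in black and 24.8 ± 9.25 in white (SD, n = 3 each; log2 fold change -6.30 ± 0.38, adjusted p = 5.6e-05). The lipid-transfer protein genes LOC105176147 and LOC105177241 had log2 fold changes of -4.57 ± 0.31 (adjusted p = 6.77e-05) and -2.06 ± 0.21 (adjusted p = 0.000369). The members higher in black included the lipid-transfer protein genes LOC105167245 and LOC105175819, described as cotyledon-specific and chosen after their values were seen. LOC105167245 had 2956 FPKM in black replicate 1, 138 and 108 in the other black libraries and 85.3 to 124 in the white, so the cultivars overlapped. Its call (adjusted p = 0.0478) was lost without black replicate 1 (adjusted p = 0.375) and without any white library (0.112, 0.151 and 0.134). It was also lost in both limma fits (0.22 and 0.225), with the replicate block (0.211) and with totals without the 100 most abundant genes (0.0596), with 0.0181 to 0.375 over all alternatives. LOC105175819 had a log2 fold change of 4.51 ± 1.27 (adjusted p = 0.0271) and of 1.16 without black replicate 1. Its call was lost without any white library (0.0678, 0.105 and 0.0918), in both limma fits (0.0925 and 0.0954) and with the replicate block (0.0619), with 0.00893 to 0.105 over all alternatives. The list passed camera (adjusted p = 1.49e-05), but not with an estimated correlation (adjusted p = 0.46).

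Cell wall genes had 68 of 190 members higher in white, 16 higher in black and 106 not called (75 and 18 when adjusted over the list alone; median -0.45, and -0.71 without black replicate 1). The galacturonosyltransferase-like gene LOC105177186 had a log2 fold change of -1.79 ± 0.19 (adjusted p = 0.000436). The xyloglucan endotransglucosylase/hydrolase gene LOC105155677, the most abundant, had 1510 ± 341 FPKM in black and 2567 ± 536 in white (SD, n = 3 each; adjusted p = 0.0387). Its call was lost without black replicate 2 or 3, without white replicate 1 or 3, with library totals, in both limma fits and with the replicate block. The adjusted p ran from 0.000713 to 0.148 over all alternatives, with 0.148 and 0.1 without black replicates 2 and 3 and 0.117 and 0.134 without white replicates 1 and 3. The cell wall list passed camera (adjusted p = 0.00027), but not with an estimated correlation (adjusted p = 0.498).

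In the general phenylpropanoid pathway, which feeds lignin, lignans and flavonoids, 5 of 12 members were higher in white, 1 higher in black and 6 not called (6 and 1 when adjusted over the list alone). The median was -1.20, with -1.99 without black replicate 1, -0.83 without black replicate 2 and -0.73 without white replicate 2. The cinnamate 4-hydroxylase gene LOC105170464 (linkage group 9, 3510172 to 3513393) had 3.64 ± 0.409 FPKM in black and 90.8 ± 38.3 in white (SD, n = 3 each; log2 fold change -4.63 ± 0.30, adjusted p = 6.62e-05). The 4-coumarate-CoA ligase 2 gene LOC105165431 had a log2 fold change of -3.87 ± 0.42 (adjusted p = 0.000483). The list's call (camera adjusted p = 0.0241) was lost without black replicate 2 (0.0679) and without white replicate 2 (0.0553). It was also lost with an estimated correlation (adjusted p = 0.601), and the adjusted p ran from 0.00316 to 0.601 over its alternatives. Class III peroxidases, which oxidize phenolics in cell walls, had 12 of 20 members higher in white, 0 higher in black and 8 not called (12 and 3 when adjusted over the list alone; median -1.27). DESeq2 called 3 higher in black, as many as at an unadjusted p under 0.05 in edgeR. Members higher in white included peroxidase 42-like LOC105175345 (-1.39 ± 0.12, adjusted p = 0.000192), peroxidase 46 LOC105164889 (-2.45 ± 0.28, adjusted p = 0.000563) and the most abundant, peroxidase 43-like LOC105169185 (-0.68 ± 0.15, adjusted p = 0.0101). That list passed camera (adjusted p = 0.000599), but not with an estimated correlation (adjusted p = 0.46).

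Genes tied to seed colour did not move in a single direction. Of 13 tested genes of the flavonoid core pathway, 3 were higher in black and 3 higher in white (the same when adjusted over the list alone; median -0.26, camera adjusted p = 0.60). The median ran from -0.77 to -0.09 on leaving out 1 library. The flavonoid 3'-monooxygenase-like gene LOC105175169 (linkage group 2, 318426 to 320565) had 0.368 ± 0.349 FPKM in black and 30.3 ± 10.8 in white (SD, n = 3 each; log2 fold change -6.42 ± 0.66, adjusted p = 0.000368). The change was -5.77 without black replicate 1 and -7.23 without black replicate 2. LOC105175177, with the same description, had 59.9 ± 9.84 FPKM in black and 32.1 ± 2.73 in white (adjusted p = 0.00303). In the anthocyanidin and proanthocyanidin branch, 3 of 25 members were higher in black and 6 higher in white (3 and 7 when adjusted over the list alone). The median was 0.10 while the mean (-0.40) and camera (adjusted p = 0.941) pointed to white, and it ran from -0.13 without white replicate 3 to 0.36 without black replicate 2. The malonyltransferase-like gene LOC105171502 had a log2 fold change of -4.65 ± 0.51 (adjusted p = 0.000476), and -5.29 without black replicate 1. The acyltransferase-like gene LOC105162663 had 1.74 ± 0.20 (adjusted p = 0.000589). LOC105178640, the most abundant, had -0.40 ± 0.14 (adjusted p = 0.0609, 0.0305 to 0.384 over all alternatives) and was called with DESeq2, the stricter filter, both limma fits and totals without the 100 most abundant genes.

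Of 9 flavonoid and seed pigment regulators, 1 was higher in black and 3 higher in white (the same when adjusted over the list alone; median -0.21, camera adjusted p = 0.347). The median was -0.34 without black replicate 1, -1.14 without black replicate 3 and -0.56 without white replicate 3. The TRANSPARENT TESTA 1 gene LOC105158965, a zinc finger regulator of seed coat pigmentation, had 0 counts in all black libraries and was at least 41.3-fold higher in white (adjusted p = 0.00176; at least 25.7-fold without black replicate 1). The MYB114 gene LOC105158544 had a log2 fold change of -3.80 ± 0.67 (adjusted p = 0.00412), and -4.57 without black replicate 1. LOC105175760, the most abundant of the list, had 30.4 ± 3.70 and 27.5 ± 3.10 FPKM (SD, n = 3 each; adjusted p = 0.438). It is described as WD repeat-containing protein LWD1, which the text pattern named, and its description names no role in pigmentation. Polyphenol oxidases, which oxidize phenols to quinones that form brown or black products, had 4 tested members of 12. Of these, 0 were called by edgeR over all genes, when adjusted over the list alone, or at an unadjusted p under 0.05, and 0 by DESeq2. LOC105176879 had 3.58 ± 3.32 FPKM in black and 1.38 ± 0.794 in white (log2 fold change 1.38 ± 0.65, adjusted p = 0.14). The aureusidin synthase gene LOC105175637 had 3.27 ± 5.26 and 0.752 ± 0.424 FPKM (adjusted p = 0.221), with 9.35 FPKM in black replicate 3. LOC105165516 and LOC105165518 had log2 fold changes of -0.55 ± 1.38 (adjusted p = 0.791) and -1.08 ± 0.65 (adjusted p = 0.239). For LOC105165518 white replicate 1 held 59 of the 94 white counts, and without it the log2 fold change was -0.05. Without black replicate 1, LOC105176879 was called with a log2 fold change of 1.77 (adjusted p = 0.0374, 0.0374 to 0.734 over all alternatives). Black replicate 2 held 332 of its 515 black counts, and without that library the log2 fold change was 0.29. LOC105165516 was called lower in black when black replicate 1 was left out (adjusted p = 0.00288, 0.00288 to 0.994 over all alternatives). The other black libraries have 0 counts of it, so it was at least 28.5-fold higher in white, and the fitted log2 fold change of -8.26 is no bound. A further polyphenol oxidase gene, LOC105176878 (linkage group 14, 3423817 to 3425759), chosen after its values were seen, did not pass the filter. It had 5946 counts (107 FPKM) in black replicate 1, 0 in the other black libraries, and 0, 4 and 0 in the white.

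Cytosolic ribosomal protein genes had the highest median among the tested lists. Of 214 tested, 162 were higher in black, 1 higher in white and 51 not called (193 and 1 when adjusted over the list alone), with a median log2 fold change of 0.64 and quartiles of 0.54 and 0.73. The L27a gene LOC105168300 had 266 ± 35.3 FPKM in black and 117 ± 26.8 in white (SD, n = 3 each; log2 fold change 1.20 ± 0.19, adjusted p = 0.00256). The L23 gene LOC105171738 had 74.8 ± 5.54 and 37.9 ± 5.43 FPKM (adjusted p = 0.00138). The most abundant, the L19 gene LOC105165211, had 1087 ± 189 and 786 ± 164 FPKM (adjusted p = 0.103), and was called with library totals and with DESeq2 (adjusted p = 0.0225 and 0.0414, and 0.0225 to 0.27 over all alternatives). The list passed camera (adjusted p = 3.33e-25), but not with an estimated correlation (adjusted p = 0.498) and not the directional fry test (adjusted p = 0.0566). Its members varied together (estimated correlation 0.893), so their calls are not independent. Against the other libraries of its cultivar, the list's median log2 difference was -0.34 in black replicate 1 and 0.32 in black replicate 3. It was 0.38 in white replicate 1 and -0.48 in white replicate 2. Of 39 genes of abscisic acid metabolism and response, 11 were higher in black, 3 higher in white and 25 not called (the same when adjusted over the list alone; median 0.39). The abscisic acid 8'-hydroxylase gene LOC105165006, of the enzyme that breaks the hormone down, had 121 ± 19.7 FPKM in black and 50.6 ± 10.7 in white (adjusted p = 0.002). The protein phosphatase 2C 37-like gene LOC105171935 had a log2 fold change of 0.81 ± 0.15 (adjusted p = 0.00531) and the ABI5-like gene LOC105155750 of -3.23 ± 0.32 (adjusted p = 0.000316). That list's call (camera adjusted p = 0.025) was lost without white replicate 2 (0.057) and with an estimated correlation (adjusted p = 0.46, and 0.0123 to 0.46 over its alternatives).

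**Figure D3:**
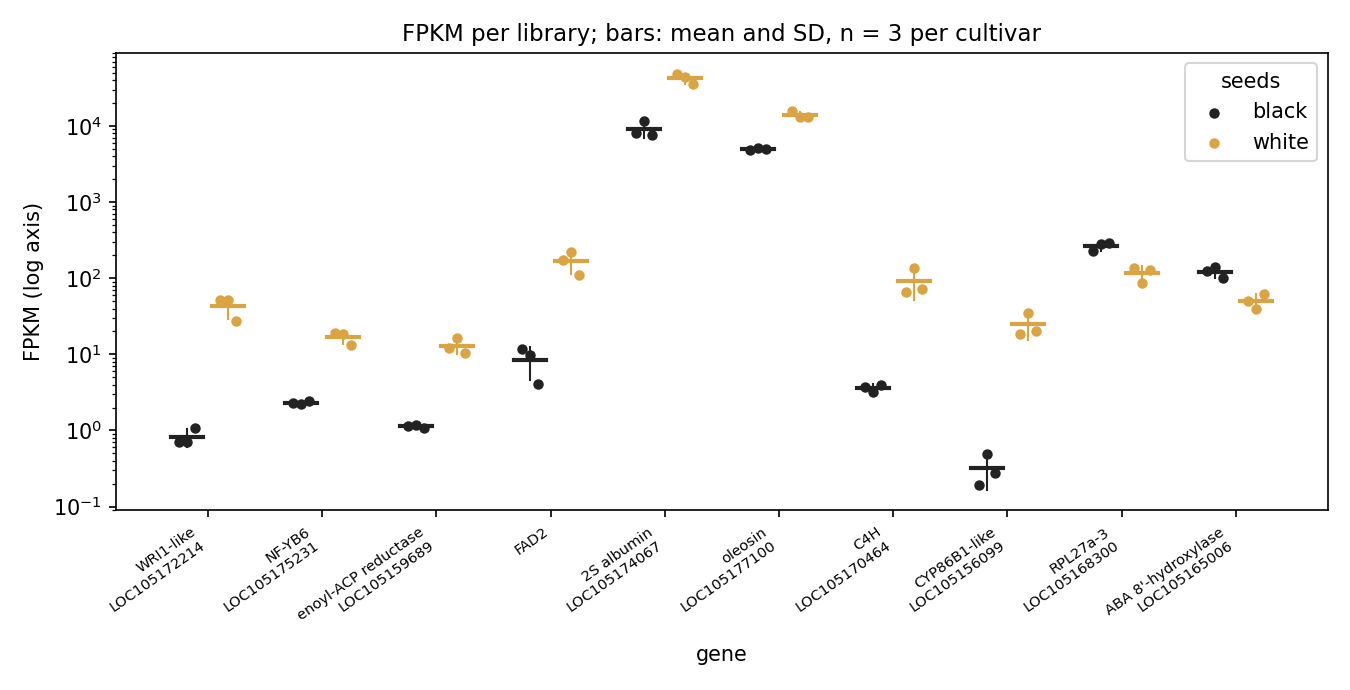
FPKM (y axis, log scale) of 10 named genes (x axis) in each black and white library, 1 point per library, with the mean and SD of 3 libraries per cultivar as bars. For each of the 10 genes the 3 black points lie apart from the 3 white points, higher in black for the ribosomal protein L27a and abscisic acid 8'-hydroxylase genes and higher in white for the others.

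Sucrose and starch genes had 27 of 80 members higher in white, 6 higher in black and 47 not called (30 and 7 when adjusted over the list alone; median -0.34, and -0.58 without black replicate 1). The stachyose synthase gene LOC105178881 and the SWEET1-like sugar transporter gene LOC105159417 had log2 fold changes of -4.59 ± 0.29 (adjusted p = 5.6e-05) and -5.39 ± 0.40 (adjusted p = 0.000108). The galactinol synthase 2 gene LOC105168975, the most abundant, had 698 ± 27.1 FPKM in black and 537 ± 126 in white (SD, n = 3 each; adjusted p = 0.157). It was called with library totals (adjusted p = 0.0353, and 0.0353 to 0.303 over all alternatives). The sucrose and starch list passed camera (adjusted p = 0.00299), but not with an estimated correlation (adjusted p = 0.498).

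Defence genes had 30 of 115 members higher in white, 11 higher in black and 74 not called (34 and 13 when adjusted over the list alone; median -0.26, and -0.49 without black replicate 1). The defensin-like gene LOC105178018 and the disease resistance gene LOC105171866 had log2 fold changes of -2.90 ± 0.26 (adjusted p = 0.000211) and -5.38 ± 0.46 (adjusted p = 0.000192). The STH-2-like gene LOC105158618, the most abundant, had 1216 ± 504 FPKM in black and 631 ± 129 in white (SD, n = 3 each; adjusted p = 0.0325). Its call was lost without black replicate 3 or white replicate 2 or 3 (adjusted p = 0.0877, 0.0995 and 0.112), in both limma fits, with the replicate block and with totals without the 100 most abundant genes (0.00115 to 0.112 over all alternatives). The list's call (camera adjusted p = 0.0201) was lost without white replicate 2 (0.057) and with an estimated correlation (adjusted p = 0.498, and 0.00328 to 0.498 over its alternatives).

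The pollen and floral list had 8 of 23 members higher in white, 1 higher in black and 14 not called (9 and 1 when adjusted over the list alone; median -0.56, and -0.33 without white replicate 2). Its members included the leucine-rich repeat extensin-like gene LOC105168047 (-1.29 ± 0.18, adjusted p = 0.00143). The receptor-like kinase gene LOC105173849 had a log2 fold change of -5.12 ± 0.81 (adjusted p = 0.00259), from 4 counts in the black libraries together, 3 of them in black replicate 1. The change ran from -6.2 to -4.58 over the alternatives that tested the gene. The most abundant, the pollen allergen-like gene LOC105176478, had -0.47 ± 0.23 (adjusted p = 0.16) and was called without black replicate 1 (-0.79, adjusted p = 0.0106, and 0.0106 to 0.449 over all alternatives). The list's call (camera adjusted p = 0.0477) was lost on leaving out any 1 of the 6 libraries (0.0617 to 0.147), with RLE scaling (0.0516) and with totals without the 100 most abundant genes (0.0812). It was also lost with an estimated correlation (adjusted p = 0.46), and the adjusted p ran from 0.0166 to 0.46 over its alternatives.

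Green tissue genes had 7 of 42 members higher in white and 3 higher in black (7 and 2 when adjusted over the list alone; median -0.24, camera adjusted p = 0.0945). Without black replicate 1 the median was -1.43 and the list passed toward white (adjusted p = 4.12e-05, and 4.12e-05 to 0.798 over its alternatives). It also passed with the replicate block (0.0428, median -0.76). Without black replicates 2 and 3 in turn the median was 0.13 and 0.14, and 0.01 without white replicate 2. With library totals it passed relative to the other genes (0.00939), with a list median of 0.00 where that of all tested genes was 0.25. With an estimated correlation it did not pass (adjusted p = 0.798). In black replicate 1, 29 of the 42 members lay more than 1 log2 unit above the mean of the other black libraries.

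The 6 largest differences toward white, by the rule for named genes, were genes with 0 counts in all black libraries, so their folds are lower bounds. A glucan endo-1,3-beta-glucosidase gene, LOC105171036 (linkage group 9, 7575073 to 7575856), had 165 ± 102 FPKM in white (SD, n = 3) and was at least 2086-fold higher than in black (adjusted p = 0.000461). The others were the peptide amidase A-like gene LOC105160973 (at least 1212-fold), the beta-xylosidase gene LOC105169195 (at least 516-fold) and NAC43, LOC105173057, a regulator of secondary walls (at least 359-fold). The basic blue protein-like genes LOC105169157 (17712083 to 17712790) and LOC105169156 (17709913 to 17710551), near each other on linkage group 8, were at least 1075-fold and at least 238-fold higher. The adjusted p of these 5 genes ran from 0.000229 to 0.0016. White replicate 2 held the most counts of each of the 6 genes, as for LOC105173057 with 103, 542 and 164 counts in the white libraries. Without it the bounds were 1427-fold for LOC105171036, 818-fold for LOC105160973, 361-fold for LOC105169195, 182-fold for LOC105173057, 676-fold for LOC105169157 and 133-fold for LOC105169156. Without black replicate 1, which leaves fewer black counts in all to set the floor against, they were 1298, 754, 321, 224, 669 and 148-fold in the same order.

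Toward black, the pathogenesis-related STH-2 gene LOC105158718 had 24.4 ± 27.2 FPKM (SD, n = 3) against 2 counts in the white libraries together, a ratio of 438 (95% Poisson interval 121 to 3613, adjusted p = 0.00226). Its fitted log2 fold change was 8.54, with 7.08 without black replicate 3. White replicate 2 holds both white counts, and without it the gene was at least 190-fold higher in black. A histone H4 gene, LOC105179910, had 54.4 ± 12.2 FPKM in black and 0.439 ± 0.0211 in white (log2 fold change 6.92 ± 0.30, adjusted p = 1.36e-05). The adenosylhomocysteinase-like gene LOC105180103 had a log2 fold change of 4.85 ± 0.38 (adjusted p = 0.000126). For the lipid-transfer protein gene LOC105171991, the P450 gene LOC105171624 and the kirola-like gene LOC105159933, black replicate 1 was over 5 times above every other library. LOC105171624 had a log2 fold change of 5.51 ± 1.05 (adjusted p = 0.00575), with 3.65 without black replicate 1 and 6.32 without white replicate 3. LOC105171991 had 6.52 ± 1.58 (adjusted p = 0.0152), with 3.51 without black replicate 1 and 8.21 without white replicate 1. Its call was lost without white replicate 2 or 3 (0.0683 and 0.0621) and with limma on log2(FPKM + 1) (0.053), with 0.000774 to 0.0683 over all alternatives. LOC105159933 had 5.02 ± 1.42 (adjusted p = 0.0276). Its call was lost without black replicate 1 (log2 fold change 1.31, adjusted p = 0.0575), without white replicate 1, 2 or 3 (0.078, 0.108 and 0.0844), in both limma fits and with the replicate block, with 0.0109 to 0.108 over all alternatives.

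By a rule of 0 to 1 count in each library of a cultivar and 10 or more in each of the other, 95 genes were detected in white and not in black seeds, and 10 the other way round. Leaving out black replicate 1 gave 192 and 13. The number for black was 18 without black replicate 2 and 17 without white replicate 2, and 13 to 15 on leaving out any other library. Whether such genes lack expression, or lack a sequence that matches the shared gene models, was not tested. Some were chosen after their values were seen. Of these, MADS-box transcription factor 6, LOC105173203, had 50, 78 and 20 counts in the white libraries and 1 in the black together. The MYB26-like gene LOC105164577 had 30, 49 and 27 counts in the white libraries and 1 in the black together. The P450 93A3-like gene LOC105159706 had 20, 15 and 153 counts in the black libraries and 0 in the white.

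The remaining lists did not pass camera. For cell cycle and DNA replication, 23 of 100 members were higher in white and 8 in black (the same when adjusted over the list alone; median -0.13, adjusted p = 0.119). For gibberellin, 11 of 34 were higher in white and 5 in black (11 and 6 when adjusted over the list alone; median -0.30, adjusted p = 0.135). With library totals both lists passed relative to the other genes (0.0417 and 0.043), with list medians of 0.09 and -0.07 where that of all tested genes was 0.25. With an estimated correlation neither passed (adjusted p = 0.533 and 0.46), and these were the highest adjusted p over their alternatives. For small heat shock proteins, 2 of 28 were higher in white and 6 in black (the same when adjusted over the list alone; median 0.25, adjusted p = 0.198). That list passed toward black without white replicate 1 (0.0383, and 0.0383 to 0.798 over its alternatives). For seed coat regulators, 3 of 11 were higher in white and 0 in black (the same when adjusted over the list alone; median -0.52, adjusted p = 0.135), with 1 higher in black at an unadjusted p under 0.05 and 0 with DESeq2. For lignin, 12 of 48 were higher in white and 5 in black (13 and 7 when adjusted over the list alone; median -0.10, adjusted p = 0.206). For tyrosine and DOPA metabolism, 3 of 10 were higher in white and 0 in black (the same when adjusted over the list alone; median -0.22, adjusted p = 0.385), with 0 higher in black at an unadjusted p under 0.05 or with DESeq2. For vacuolar transport, 12 of 75 were higher in white and 11 in black (13 and 12 when adjusted over the list alone; median -0.13, adjusted p = 0.556). On leaving out 1 library the medians ran from -0.24 to -0.05 for the cell cycle, -0.36 to -0.21 for gibberellin, 0.13 to 0.34 for small heat shock proteins and -0.62 to -0.26 for seed coat regulators. They ran from -0.22 to -0.07 for lignin, -0.25 to -0.18 for tyrosine and DOPA and -0.16 to -0.08 for vacuolar transport.

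Other lists had a median that differed in sign from the mean or from the direction of camera. For seed maturation and desiccation, 6 of 40 members were higher in white and 3 in black (5 and 3 when adjusted over the list alone), with a median of 0.02, a mean of -0.27 and camera toward white (adjusted p = 0.687). Its text pattern also matched a gene described as a putative GEM-like protein, called higher in white, whose description names no such role. For fatty acid breakdown, 7 of 30 were higher in white and 4 in black (7 and 7 when adjusted over the list alone), with a median of 0.06, a mean of -0.20 and camera toward white (adjusted p = 0.941). For chlorophyll metabolism, 7 of 26 were higher in white and 1 in black (the same when adjusted over the list alone), with a median of 0.03, a mean of -0.11 and camera toward white (adjusted p = 0.354). For endosperm regulators, 2 of 8 were higher in white and 2 in black (the same when adjusted over the list alone), with a median of -0.19, a mean of 0.10 and camera toward white (adjusted p = 0.802). For carotenoids, 4 of 30 were higher in white and 6 in black (4 and 7 when adjusted over the list alone), with a median of 0.12, a mean of -0.15 and camera toward black (adjusted p = 0.596). For ethylene, 17 of 122 were higher in white and 27 in black (19 and 28 when adjusted over the list alone), with a median of 0.18, a mean of -0.05 and camera toward black (adjusted p = 0.18). For dirigent proteins and lignan reductases, 2 of 9 were higher in white and 2 in black (2 and 3 when adjusted over the list alone), with a median of 0.34, a mean of -0.31 and camera toward black (adjusted p = 0.588). For stress and wounding, 31 of 210 were higher in white and 32 in black (the same when adjusted over the list alone), with a median of 0.00, a mean of -0.11 and camera toward black (adjusted p = 0.941). On leaving out 1 library the median ran from -0.14 to 0.04 for seed maturation, -0.05 to 0.15 for fatty acid breakdown, -0.08 to 0.24 for chlorophyll and -0.03 to 0.04 for stress and wounding. It ran from -0.30 to -0.10 for endosperm regulators, 0.02 to 0.22 for carotenoids, 0.16 to 0.20 for ethylene and 0.29 to 0.58 for dirigent proteins and lignan reductases. Laccases had 1 of 3 tested members higher in white and 0 in black, and organelle-encoded genes had 0 of 3 called, too few for a list test. At an unadjusted p under 0.05 the organelle-encoded genes had 1 higher in white, and DESeq2 called 0.

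The authors' deposited table holds 6487 genes at an adjusted p under 0.05, of which 2795 were higher in black and 3692 higher in white. Of the 5937 genes called here with edgeR, 5726 were among those of the authors' deposited table, and 0 of them had the opposite direction there.

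**Figure D4:**
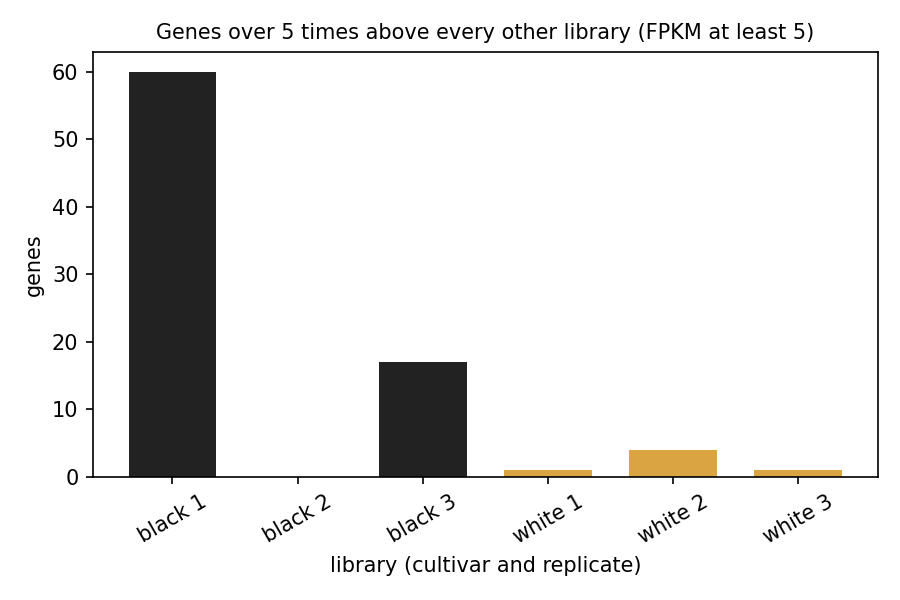
Number of genes (y axis) with an FPKM of 5 or more and over 5 times that of every other library, for each of the 6 libraries (x axis, 1 bar per library). Black replicate 1 had 60 such genes and black replicate 3 had 17, against 0 to 4 in the others.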

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

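Totals without the 100 most abundant genes, and library totals for the gene lists, were chosen after seeing the data, as was naming some of the genes. The count of called genes (5937) stayed within 1.5 times under DESeq2, the other scalings, both filters and both limma fits (4811 to 8022). That of genes differing at least 2-fold (2621) did so except under the stricter filter (1540), which tests fewer genes. Leaving out 1 library gave 3433 to 6124 called genes, 1747 to 3174 at least 2-fold, 10 to 14 passing lists and 119 to 205 genes detected in 1 cultivar only, from fewer libraries. A rule of 0 counts against 50 or more gave 17 such genes, with both limits of the rule changed at once. Of the 14 passing lists, 0 passed camera with an estimated correlation (lowest adjusted p = 0.46, 2 lists at an unadjusted p under 0.05). With fry, 19 lists passed the directional test and 33 the mixed test, which asks whether members change in either direction. With the replicate block, 3939 genes and 15 lists were called. Same-numbered black and white libraries did not deviate together from their cultivar means (correlations across genes, which are not independent replicates, of -0.08, -0.17 and -0.03), so the numbers were not taken as pairs. Of 76 named genes tested, 65 were called, and 55 of these stayed past the threshold in every alternative that tested them. Many were named for a small adjusted p or a large change in these data, so this does not carry over to all called genes. Of the 5937 called genes, 2562 were not called without white replicate 2, 2501 without black replicate 2 and 2048 with the replicate block. For 3 of the named genes the direction turned in some alternative. LOC105165516 (not called) turned to 0.02 without black replicate 2 and 0.03 without black replicate 3, and ranged down to a fitted -8.26 on leaving out 1 library. LOC105175637 (not called) turned to -0.04 with the replicate block, and ranged from -1.61 to 2.72 on leaving out 1 library. LOC105177087 turned to -0.02 without black replicate 1, which holds nearly all its counts, and ranged up to 7.23. For the other changes the cause was not tested. GO or KEGG terms were not run, because the tables do not pair genes with them, nor was the pseudocount of 0.01, planned for FPKM as the main unit. The depth of 18063717 to 25664204 counts limits what can be said of genes near 3 counts. In simulation 39.4% of 2-fold changes were recovered with 3 libraries per cultivar. Far fewer genes were changed there than were called in the data, so that share may not hold here.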

Other observations

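The tests of seed stage, of scaling on the ribosomal protein genes, of green tissue and of protein families, the totals without the 100 most abundant genes, and the bootstrap intervals were chosen only after the results were seen. The bootstrap intervals took the place of member quartiles and measure the median, not the spread of members. For green tissue in black replicate 1 the quartiles were 0.54 and 3.25, wider than the bootstrap interval given below. Protein families named in the deposited table were tested for enrichment among the genes called by edgeR (one-sided hypergeometric test, background 7196 tested genes with a family, Benjamini-Hochberg adjustment). The test takes genes as independent draws, so its adjusted p may be too small for genes that vary together. It is given for the calls with TMM factors. The 2715 genes higher in black there became 1886 to 5599 with the other scalings. Among genes higher in black, 63 of 187 genes of RRM_1, a family of RNA-binding proteins, were found (24.6 expected, adjusted p = 7.44e-11). GTP_EFTU, the translation factor type GTPases, had 19 of 28 (3.68 expected, adjusted p = 5.96e-09). The DEAD helicases had 27 of 60 (7.88 expected, adjusted p = 1.59e-07), and KH_1, also RNA-binding, had 13 of 26 (3.41 expected, adjusted p = 0.000469). Among genes higher in white, Lipase_GDSL had 26 of 49 (8.99 expected, adjusted p = 3.91e-06) and Peptidase_S10, the serine carboxypeptidases, had 14 of 26 (4.77 expected, adjusted p = 0.00298). Kinesin had 19 of 47 (8.62 expected, adjusted p = 0.0123), and SRF-TF, the MADS-box factors, had 10 of 19 (3.48 expected, adjusted p = 0.0258). Also passing were zf-CCCH (12 of 27, adjusted p = 0.00339) and WD40 (15 of 50, 0.0422) toward black, and Biotin_lipoyl (8 of 11, 0.00566) and p450 (50 of 167, 0.00647) toward white. Among genes differing at least 2-fold, RRM_1, GTP_EFTU, DEAD and KH_1 each had 0 genes higher in black. There p450 passed in both directions, with 17 of 167 higher in black (3.92 expected, adjusted p = 5.82e-05) and 43 higher in white (20.2 expected, adjusted p = 9.99e-05). MatE (6 of 43, adjusted p = 0.0176), 2OG-FeII_Oxy (7 of 68, 0.0288), AP2 (8 of 95, 0.0418), UDPGT (8 of 97, 0.0418) and Sulfate_transp (3 of 11, 0.0418) also passed toward black at 2-fold. ABC2_membrane (12 of 32, adjusted p = 0.0109), Cyclin_C (11 of 28, 0.0109), Abhydrolase_3 (11 of 30, 0.0176), HMA (11 of 31, 0.0222) and DUF6 (9 of 25, 0.0418) passed toward white at 2-fold only, beside the families that passed toward white without that limit.

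The higher level of fatty acid synthesis genes in white seeds went with a storage protein share of 19.1% to 26.6% of counts there against 3.90% to 7.22% in black, which may shift the scaling between libraries. With totals without the 100 most abundant genes the list's median log2 fold change was -1.62 (bootstrap interval over members -1.89 to -1.18). That scaling moved tested genes toward white (median shift -0.1), so it could not have weakened the pattern. Library totals moved them toward black (median shift 0.22), and the list's median was then -1.29. Both shifts were small beside the list's median, which argues against the choice among these scalings as the whole cause. The highest median over the fits without 1 library was -1.33 (lowest -1.67), which argues against a single library as the cause. Seeds of different developmental stages stay open, since the median of the seed maturation and desiccation list was 0.02 (-0.42 to 0.21) and the labels give no seed age, so stage and cultivar cannot be told apart. A difference between the cultivars as such also stays open and untested.

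The higher level of cytosolic ribosomal protein genes in black seeds (median 0.64) could come from short genes being favoured in the black libraries. Over 1000 sets of other genes matched on length and mean expression, the median was 0.14 (95% of sets 0.03 to 0.26) and 0 sets reached 0.64, which argues against length as the whole cause. Over RLE, library totals and totals without the 100 most abundant genes, the lowest median of the list was 0.54 (bootstrap interval 0.53 to 0.56), with the last of these. A change of scaling moves nearly all genes by a common amount, here by a median of -0.01, 0.22 and -0.1 in the same order. Shifts of that size could not have removed a median of 0.64, so the outcome followed from them. The values show only that these scalings differ by less than the list's median. An error shared by all of them was not tested. The bootstrap interval resamples list members, which vary together, so it does not measure the spread between libraries. With TMM factors the list's median ran from 0.50 without white replicate 2 to 0.80 without white replicate 1. Developmental stage and cultivar stay open as untested explanations.

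Black replicate 1 had 60 genes over 5 times above every other library, among them, chosen after their values were seen, the fatty-acid-binding protein 1-like gene LOC105177087 (418 FPKM against at most 1.96) and the RuBisCO small chain gene LOC105178031 (161 against at most 5.64), for both of which the cultivars overlapped. The median member of the green tissue list lay 1.57 log2 units (bootstrap interval 1.10 to 2.66) above the mean of the other black libraries, which is consistent with green tissue, or greener seeds, in that sample as a hypothesis. Of the list's 61 members 42 passed the filter in these seeds, 1 of them with 0 counts in all black libraries and 0 of them in another list, 8 of the 60 genes are members, and the most abundant of the list in that library is LOC105178031. Germinating seed or seedling tissue stays open, since the median of the fatty acid breakdown and glyoxylate cycle list was 0.30 (0.05 to 0.47) and 0 of the 60 genes belong to it. The labels give no difference between the black libraries, so no explanation from the design was tested.

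In black replicate 3, the thaumatin-like gene LOC105157575 had 164 FPKM against at most 3.54 elsewhere, and the acidic endochitinase gene LOC105166719 had 102 against at most 3.11, both chosen after their values were seen. For both, the other black libraries overlapped the white ones. The call of LOC105157575 (adjusted p = 0.0294) was lost without black replicate 3 (0.133), without any white library (0.0893, 0.094 and 0.101), in both limma fits (0.135 and 0.102) and with the replicate block (0.0827), with 0.00654 to 0.135 over all alternatives.

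Splitting the 6 libraries into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split called 5937 genes and 2621 at least 2-fold, the highest in 1 of the 10 splits each, against a highest other value of 0 for both. Every other split mixes both cultivars in each group, so the difference between cultivars adds to the spread within groups and holds calls down. The value of 0 therefore does not measure what chance gives, and no conclusion is drawn from it. For the gene lists, 14 passed in the real split against a highest other value of 16, and 3 splits reached 14 or more.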
